A study of Mus musculus with 2 samples.

How the data were processed

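Nuclei were isolated from snap-frozen whole spinal cords of AR-97Q and AR-24Q mice, 1 pool per genotype, cleaned with a debris removal solution, sorted by DAPI fluorescence and run on the 10x Genomics GEM-X 3' gene expression assay, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode: the authors made them with Cell Ranger 9.0.1 on mm10, per the submitters' processing notes, and whether introns were counted and how the transgene was handled are not given in the sources used here. The deposited matrices hold 33696 genes in 2 libraries and 40465 barcodes, and all values are whole numbers. The features carry gene identifiers and symbols, of which 32012 identifiers occur in the GENCODE M21 annotation of GRCm38 and 1684 do not, so coordinates are given only for genes found there. No column of per-sample values was left unused.

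Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs were kept, which left out 88 AR-24Q and 319 AR-97Q barcodes for genes and 0 and 4 for mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 10%), which marked 656 AR-24Q nuclei (3.57%) and 1078 AR-97Q nuclei (4.88%) above its own thresholds of 0.370 and 0.312, and these were left out. That left 38383 nuclei. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were scaled with values limited to 10, and both libraries were clustered together without correction for library (30 principal components, 15 neighbours, Leiden resolution 1, seed 1), with leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and anndata 0.12.19 under Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

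The 49 clusters were named from markers fixed before the data were examined. A cluster stayed unnamed when fewer than 3 markers of its nearest class were detected at 10 UMIs or more, when more markers of another class than of its own were among its top 10 genes, when its median UMIs were more than 3-fold under those of the library in at least 1 of the 2 libraries with no marker of its class among the top genes, or when it held a second class at high UMIs. This left 4 clusters unnamed. The neuron class was clustered again into 53 subclusters. Subclusters with 2 or more markers of another class among their top 10 genes were set aside as mixed (4). Another 4 were left without a subclass because no subclass score was 2 times the next or fewer than 3 markers of the subclass were detected. The scoring thresholds, the limits for mixed and high-UMI clusters and the minimum score of 0.5 for cerebrospinal fluid-contacting neurons were set after the clusters were seen.

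With 1 library per genotype no model was fitted and no p-value computed. Shares of nuclei are given with exact Clopper-Pearson 95% intervals. Within each class of at least 100 nuclei in both libraries, UMIs were summed per library and divided by the class total (CPM), with exact Poisson intervals, and the ratio of AR-97Q to AR-24Q has the exact conditional binomial 95% interval. Summed UMIs per class ranged from 434963 (endothelial, AR-24Q) to 105054751 (neurons, AR-24Q). These intervals cover counting error only. A gene met the size rule when it was at least 1.5-fold apart with the interval off 1, and genes entered the count with at least 50 CPM and 100 UMIs in the higher library. Named genes followed a rule written before the data were examined: the first 10 higher and 10 lower by ratio in oligodendrocytes, astrocytes, neurons and microglia and the first 4 each way in other classes, leaving out mitochondrial, ribosomal protein and predicted genes, Xist, Tsix and 4 Y-linked genes (other X-linked genes stayed in) and genes more than 10-fold under their level in the highest class, plus the first 8 each way shared by most classes, Ar, and members of the fixed lists. Fewer than 10 are named where fewer met the rule.

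For each of 31 gene lists fixed beforehand, the median log2 ratio was taken over members with at least 10 CPM in the higher library when 5 or more were measured, with the exact order-statistic 95% interval of a median over members, and the percentile of the median among 10000 random lists of the same size, matched on expression in 25 bins. The percentile describes these 2 libraries. A list member met the size rule on ratio and interval alone. Which lists are given for which class was chosen after the medians were seen. The steps were tested on simulated counts drawn from the real means with 50 genes changed at each fold. In oligodendrocytes (3179 genes) the rule recovered 0% at 1.25-fold, 30% at 1.5-fold and 100% at 2-fold, and in endothelial nuclei (941 genes) 6%, 40% and 88%. Among unchanged genes it called 0 in oligodendrocytes, 2 in endothelial nuclei and 3 in microglia, the most of any class. The simulated counts were Poisson draws without spread between nuclei, mice or libraries. These numbers therefore cover counting error only.

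Shares of classes were recomputed with other gene minimums (200 and 1000), doublet calls kept, Leiden resolutions of 0.5 and 2 and components centred per library, and shares of neuron subclasses with doublet calls kept and at resolution 2. Gene ratios, counts by the size rule and list medians were recomputed with doublet calls kept, a minimum of 1000 genes, edgeR 4.0.16 TMM scaling (R 4.3.3; no edgeR model was fitted), median-of-ratios scaling, the mean of each nucleus's own CPM (no counts by the rule) and nuclei thinned to 1000 UMIs. The counts were also made at 20 CPM and 50 UMIs, and list medians without a floor, at 50 CPM and without members that can be free RNA. Thinning left out 62 AR-97Q microglia and at most 8 nuclei of any other class and library. A setting that keeps mixed neuron clusters in the neuron class was added after the data were seen, for shares, gene ratios and list medians. Pericytes, ependymal cells and fibroblasts were too few for gene comparisons.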

Results

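Transcripts were counted in single nuclei of whole spinal cord from 8-week-old mice, which the submitters call an early stage, in 2 libraries, 1 from AR-97Q and 1 from AR-24Q mice. AR-97Q mice are a transgenic model of spinal and bulbar muscular atrophy, a disease of motor neurons and muscle caused by an expanded glutamine tract in the androgen receptor. AR-24Q mice carry a receptor with a tract of normal length and served as the control. Each library was a pool of spinal cords, from 4 mice per genotype in the extraction protocol and from 3 in the series design. The AR-24Q library held 18372 barcodes and 178841777 UMIs, with medians of 6529 UMIs and 2597.5 genes per nucleus. The AR-97Q library held 22093 barcodes and 156649575 UMIs, with medians of 4588 UMIs and 2026 genes. The median share of mitochondrial UMIs was 0.0107% and 0.0124%. After filtering and removal of doublet calls, 17643 AR-24Q and 20740 AR-97Q nuclei were kept. With 1 pooled library per genotype there was no replicate check and no test: every difference compares these 2 libraries, not the genotypes. The 95% intervals of shares, levels and ratios cover counting error only. Those of list medians cover the spread over list members, not counting error or differences between mice. Levels are UMIs summed over the nuclei of a class, scaled to the total of the class (CPM), with AR-24Q given first.

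The first comparison was of the androgen receptor itself. Ar (ENSMUSG00000046532; chromosome X, 98148769 to 98323215 on the plus strand of GRCm38, protein-coding) was highest in neuron-like nuclei among the 7 main classes with at least 100 nuclei in each library, at 54.3 and 59.0 CPM, a ratio of AR-97Q to AR-24Q of 1.09 (1.05 to 1.13). The ratio was 1.13 (1.06 to 1.21) in excitatory, 1.08 (1.01 to 1.16) in inhibitory and 1.07 (0.883 to 1.30) in cholinergic and motor neurons. When every nucleus was thinned to 1000 UMIs these values became 1.36, 0.888 and 0.889, so no direction is drawn for Ar in the inhibitory or the cholinergic and motor neurons. In oligodendrocyte-like nuclei Ar stood at 1.99 and 5.12 CPM, 2.57-fold higher in the AR-97Q library (1.96 to 3.40), far below the neuronal level. Astrocytes had 10.9 and 12.9 CPM (ratio 1.19, 0.832 to 1.69) and endothelial nuclei 32.2 and 36.3 CPM (ratio 1.13, 0.561 to 2.36; 4.76 after thinning). In oligodendrocyte precursors the ratio was 0.828 (0.554 to 1.23), and 0.512 after thinning. Microglia held 5 and 7 Ar UMIs, and newly formed oligodendrocytes 4 and 0. The tables used here have 0 rows for a human receptor, and how far reads of the transgene were counted under Ar is not given in the sources used here, so these values do not check the genotype labels.

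The makeup of the cord was compared next, to see which cell classes differed in share. Neuron-like nuclei made up a smaller part of the AR-97Q library, 29.5% (28.8 to 30.1) against 35.1% (34.4 to 35.8), and so did astrocyte-like nuclei, 4.95% (4.66 to 5.25) against 7.53% (7.14 to 7.93). Oligodendrocyte-like nuclei were 45.9% (45.2 to 46.6) against 42.6% (41.9 to 43.4), and endothelial-like nuclei 1.17% (1.03 to 1.32) against 0.720% (0.600 to 0.856), with 242 and 127 nuclei. Ependymal-like nuclei, the ciliated lining of the central canal, numbered 29 against 52 (0.140%, 0.0937 to 0.201, against 0.295%, 0.220 to 0.386). Microglia-like nuclei were 5.47% (5.16 to 5.79) against 4.41% (4.11 to 4.72), a ratio of 1.24. That ratio was 1.01 when nuclei with at least 200 genes were kept, so no direction is drawn for microglia. Oligodendrocyte precursors (4.11% against 4.04%), newly formed oligodendrocytes (1.09% against 1.01%) and pericytes (0.501% against 0.550%) had overlapping intervals, and fibroblasts numbered 25 against 17.

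Cholinergic and motor neurons, the group that holds the cells lost in this disease, were 107 nuclei in each library, 1.75% (1.44 to 2.11) of AR-97Q and 1.73% (1.42 to 2.09) of AR-24Q neurons. Excitatory neurons were 44.8% against 42.7% of neurons and inhibitory neurons 34.0% against 34.3%, with 19.0% and 20.5% left without a subclass. Cerebrospinal fluid-contacting neurons numbered 27 against 51, 0.442% (0.292 to 0.643) against 0.824% (0.614 to 1.08) of neurons. Names were rebuilt from fixed markers, and "-like" is left out from here on. The thresholds that kept mixed and unnamed clusters out of classes were set after the clusters were seen. Neuron clusters with markers of another class held 2.49% (2.28 to 2.71) of AR-97Q and 1.48% (1.31 to 1.67) of AR-24Q nuclei, and unnamed clusters 4.6% (4.32 to 4.90) and 2.17% (1.96 to 2.40). The largest unnamed cluster, nearest to neurons, held 681 AR-97Q and 149 AR-24Q nuclei at medians of 2055 and 1669 UMIs. Counting these clusters as neurons brought the neuron ratio from 0.84 to 0.939. Nuclei had been sorted by DAPI and needed 500 genes, and median depth of the kept nuclei differed (6376 UMIs in AR-24Q, 4521.5 in AR-97Q), and each of these can set shares.

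**Figure D1:**
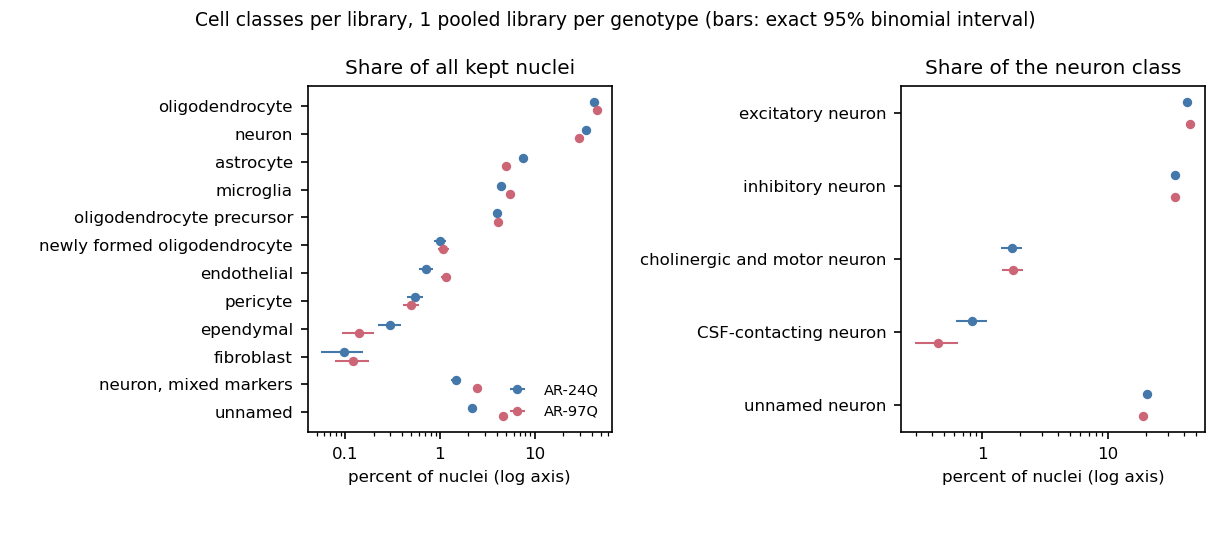
Share of all kept nuclei (left) and of the neuron class (right) in percent on a log axis, for the AR-24Q (blue) and AR-97Q (red) library. Points are shares and bars exact 95% binomial intervals; neurons (35.1% against 29.5%) and astrocytes (7.53% against 4.95%) lie lower in the AR-97Q library, and the cholinergic and motor neuron shares overlap (1.73% and 1.75%).

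In oligodendrocytes the AR-97Q library had more of Zbtb16, a zinc-finger transcription factor (136 and 257 CPM, ratio 1.89, 1.82 to 1.95), of Sgk1, the serum- and glucocorticoid-regulated kinase (ratio 1.79, 1.72 to 1.86), and of Errfi1, a feedback inhibitor of the epidermal growth factor receptor (ratio 1.81, 1.75 to 1.88). Fabp5, a fatty acid-binding protein, was 1.99-fold higher (1.87 to 2.12) and Oxr1, which protects cells from oxidative damage, 1.91-fold higher (1.86 to 1.95). Map7d2 (1.82, 1.72 to 1.92), Polr3e, a subunit of RNA polymerase III (1.69, 1.63 to 1.76), and Slc6a1, a GABA transporter (1.68, 1.60 to 1.76), were also higher. Tmem150c was 2.78-fold lower in the AR-97Q library (90.8 and 32.7 CPM, 2.60 to 2.97), the semaphorin Sema5a 1.91-fold lower (1.86 to 1.95) and the cAMP phosphodiesterase Pde4d 1.70-fold lower (1.65 to 1.76). Cracd (1.65-fold, 1.59 to 1.71), Thsd4 (1.59-fold, 1.54 to 1.65) and Nol4l (1.58-fold, 1.48 to 1.68) completed the lower side. Of 3178 genes with enough UMIs, 18 met the size rule higher and 6 lower in the AR-97Q library, and 99.2% lay within 1.5-fold.

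Among the gene lists fixed beforehand, the disease-associated oligodendrocyte list stood highest, with a median log2 ratio of 0.29 (95% interval 0.04 to 0.63) and 8 of 9 measured members above 1. Sgk1 led it, with the steroid receptor co-chaperone Fkbp5 at 1.55 (1.42 to 1.69) and the alarmin Il33 at 1.47, while Stat3 was at 0.848. Its percentile among 10000 random lists of like expression was 100. That was not particular to it, since synaptic (median 0.19), nuclear-encoded oxidative phosphorylation (0.13) and ribosomal protein genes (0.20) were at 100 too. Sgk1 and Fkbp5, its members that met the size rule, are also in the androgen response list, and free RNA is possible for Fkbp5 here. Chaperones, a list that holds the mitochondrial Hspd1 and Hspe1 beside cytosolic genes, had a median of -0.17 (-0.22 to -0.02) and 14 of 18 members below 1, among them Bag3 at 0.649 (0.572 to 0.734) and Hsp90aa1 at 0.816. With a floor of 50 CPM that median was -0.04. Myelin genes were split, with 11 members above and 8 below 1 (median 0.10, -0.05 to 0.13, and 0.04 after thinning), though the unthinned median was at a percentile of 99.8. Mog was at 1.17, Plp1 at 0.983 and Mbp at 0.95. The androgen response list split 11 above to 9 below 1 (median 0.03, -0.06 to 0.16; -0.01 when each nucleus counted equally), with Zbtb16, Sgk1, Fkbp5 and the clock gene Per1 (1.68, 1.53 to 1.84) meeting the size rule. Cholesterol synthesis (0.03) and transforming growth factor beta signalling (-0.12, -0.22 to -0.03) had percentiles of 96.6 and 5.78, and the first turned to -0.03 when each nucleus counted equally. Neuronal transcripts were also higher in this class: the neurofilament genes Nefm (1.73), Nefh (1.63) and Nefl (1.59) and the neuronal tubulin Tubb3 (1.68) met the size rule, and the neuron markers Meg3 and Snap25 were at 1.44 (1.38 to 1.50) and 1.33 (1.22 to 1.44). The median of the neurofilament and axonal transport list was 0.03 (-0.04 to 0.67).

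**Figure D2:**
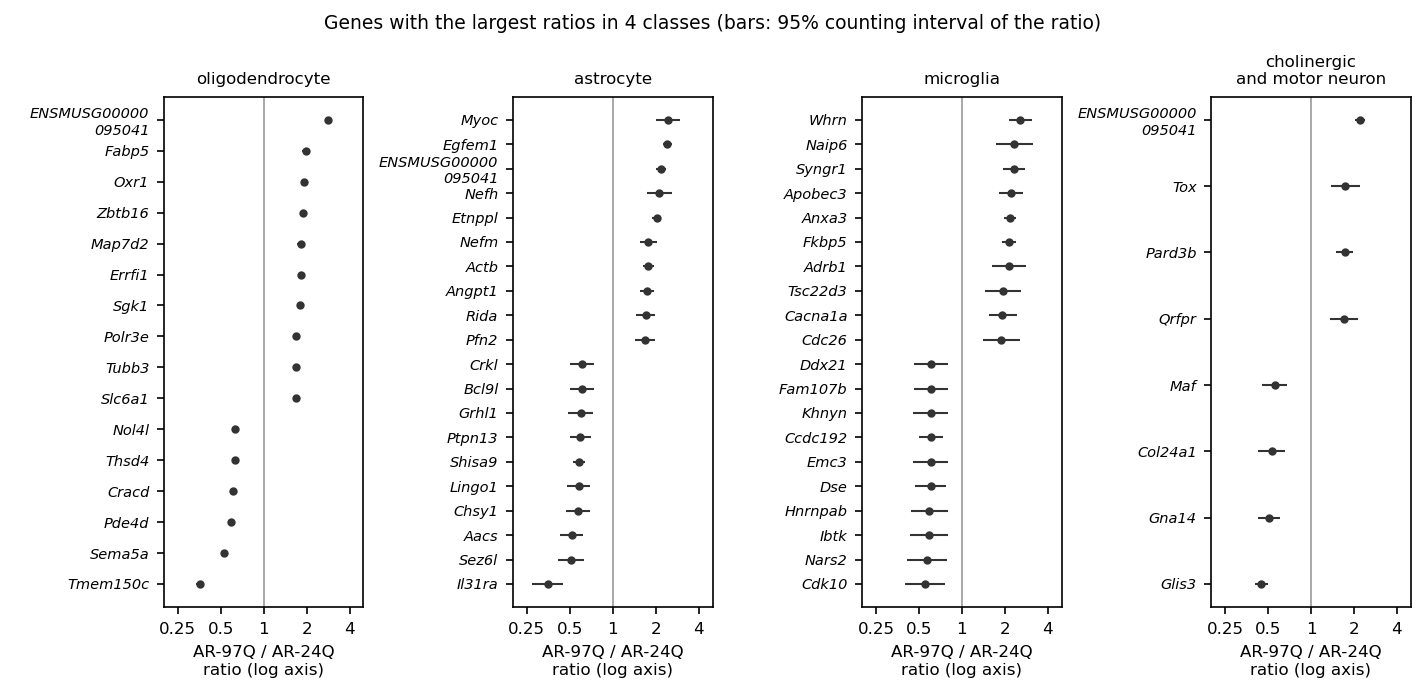
Ratio of CPM in the AR-97Q to that in the AR-24Q library (log axis) for the genes named by the size rule in oligodendrocytes, astrocytes, microglia and cholinergic and motor neurons. Points are ratios, bars 95% counting intervals and the grey line equality; values run from 0.351 for Il31ra in astrocytes to 2.81 for ENSMUSG00000095041 in oligodendrocytes.

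Neurons differed little between the libraries in single genes above the floor of 50 CPM. Of 3471 such genes, 1 met the size rule: ENSMUSG00000095041, at 310.4 and 689.9 CPM, 2.22-fold higher in the AR-97Q library (2.19 to 2.25). Setx, which encodes the helicase senataxin (ENSMUSG00000043535; chromosome 2, 29124181 to 29182471 on the plus strand, protein-coding), was 1.50-fold lower (151 and 101 CPM, 1.46 to 1.54), just short of the rule. In excitatory neurons these genes were at 2.20 (2.15 to 2.25) and 1.51-fold lower (1.44 to 1.59), and in inhibitory neurons at 2.24 (2.19 to 2.30) and 1.50-fold lower (1.44 to 1.57), the only genes to meet the rule there. Below the floor Il31ra was at 0.432, Zfp33b at 1.86 and Tatdn3 at 1.76. With the rule at 20 CPM, 7 genes met it in neurons, and with thinned nuclei 4.

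Small shifts ran together in some lists. Of 19 measured cholesterol synthesis genes 18 were lower in AR-97Q neurons (median -0.19, -0.32 to -0.16, percentile 0.01), among them Idi1 at 0.740 (0.693 to 0.791), the squalene epoxidase Sqle at 0.744 (0.704 to 0.785) and Dhcr7 at 0.788. The medians were -0.18 in excitatory and -0.18 in inhibitory neurons, with 17 of 18 and 18 of 19 members below 1. Chaperones had 15 of 16 members below 1 (median -0.11, -0.20 to -0.04, percentile 1.82), with Hsph1 at 0.694 (0.664 to 0.724) and the mitochondrial chaperonin Hspe1 at 0.727. Their median was -0.07 in excitatory and -0.08 in inhibitory neurons, at percentiles of 20.1 and 15. The unfolded protein and integrated stress response list had 12 of 13 members below 1 (median -0.12, -0.22 to -0.02, percentile 5.76, so inside the central 95% of random lists). The androgen response list had 20 of 22 (median -0.13, -0.19 to -0.04, percentile 0.14, with percentiles of 6.21 in excitatory and 1.13 in inhibitory neurons). That list shares Hmgcs1, Hmgcr, Idi1 and Dhcr24 with the cholesterol synthesis list, so these lists are not separate. The p53 and DNA damage list had 5 of 6 below 1, with Plk2 at 0.719 and Zmat3 at 0.791 and Bax at 1.13 (list median -0.19). Synaptic adhesion and transmission genes split 26 above to 14 below 1 (median 0.06, percentile 99.7). Nuclear-encoded oxidative phosphorylation genes had a median of 0.02 at a percentile of 99.99, with 0.14 in excitatory (27 of 34 above 1) and 0.03 in inhibitory neurons. Androgen receptor coregulators (-0.06), voltage-gated ion channels (-0.02), neurofilament and axonal transport (-0.04), autophagy and lysosome (-0.07) and proteasome genes (-0.01, percentile 97.65) were near 0. TMM and median-of-ratios scaling add 0.06 and 0.07 to every neuron median, which leaves cholesterol synthesis at -0.13 and -0.12, chaperones at -0.04, androgen response genes at -0.06 and the unfolded protein list at -0.06 and -0.05, and takes synaptic genes to 0.13, while the coregulator, ion channel, neurofilament and proteasome medians turn above 0. Mitochondrially encoded genes had a median of 0.30 and oligodendrocyte transcripts, listed as free RNA, one of 0.34 in these neurons (0.81 with the mixed clusters kept).

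Chaperone genes stood lower in cholinergic and motor neurons of the AR-97Q library, though less so after thinning. Of 19 measured chaperone genes 18 were below 1, with a median of -0.40 (-0.63 to -0.27) that lay below all 10000 random lists, and 4 met the size rule. Thinned to 1000 UMIs per nucleus the median was -0.23 at a percentile of 22.56, so it no longer stood out from random lists. The small heat shock protein gene Hspb1 was 2.03-fold lower (92 and 32 UMIs, 1.35 to 3.14), the mitochondrial chaperonin Hspd1 1.86-fold (1.41 to 2.48), Hsph1 1.68-fold (1.33 to 2.13) and the constitutive Hsc70 gene Hspa8 1.58-fold (1.27 to 1.98). Among single genes, the transcription factor Glis3 was 2.23-fold lower (341 and 153 CPM, 2.01 to 2.48), the G protein subunit Gna14 1.97-fold (1.66 to 2.35), the collagen Col24a1 1.89-fold (1.52 to 2.36) and the transcription factor Maf 1.79-fold (1.47 to 2.19). Higher were ENSMUSG00000095041 (2.21, 2.05 to 2.38), Tox (1.74, 1.38 to 2.19), Pard3b (1.72, 1.50 to 1.97) and Qrfpr (1.70, 1.36 to 2.14). Of 3179 genes 12 met the size rule higher and 18 lower. After thinning 3 met it higher and 0 lower, with 0 shared with the unthinned set. That count cannot show whether the differences were lost. It kept the minimum of 100 UMIs, which genes at the level of Glis3 cannot reach in 107 nuclei of 1000 UMIs. At 20 CPM and 50 UMIs 40 met it higher and 105 lower. The chaperone list did not stand lower in every class. Its median was 0.18 (-0.09 to 0.39) in astrocytes, with 12 of 19 members above 1. In endothelial nuclei it was 0.24 (-0.05 to 0.72), with 13 of 21 above 1.

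In these neurons 13 of 19 neurofilament and axonal transport genes were below 1 (median -0.11, percentile 0.52), with Nefm at 0.779 (0.709 to 0.855) and peripherin, Prph, at 0.808. Alpha motor neuron genes went both ways (median -0.06, -0.29 to 0.77): Vipr2 was at 1.71 (1.33 to 2.20), Rbfox3 at 0.831 and Chodl at 0.815. Lists of cholesterol synthesis (-0.10; Fdps 0.583), synaptic (0.08), transforming growth factor beta signalling (0.06; Tgfb2 0.605), axon injury (-0.08) and androgen response genes (-0.10; Fkbp5 0.689, Zbtb16 0.812) had percentiles between 11.9 and 98.4. The class rested on 107 nuclei per library with median depths of 32317 and 22943 UMIs, and thinning left few UMIs per gene. Thinned ratios were 0.25 for Hsph1, 0.3 for Hspa8, 1.00 for Hspd1, Fdps and Tgfb2, 0.273 for Col24a1, 0.25 for Maf, 3.5 for Tox and 0.667 for Vipr2, and thinned medians were -0.24 for neurofilament, -0.80 for alpha motor neuron, 0.26 for androgen response and 0.10 for axon injury genes. Glis3 was also a leading gene of 1 of the subclusters in the class, which held 50 AR-24Q and 45 AR-97Q nuclei. Oligodendrocyte transcripts were higher in this class too, with a list median of 1.02, Plp1 at 1.75 (1.51 to 2.02) and Mbp at 1.39 (1.15 to 1.68).

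Astrocytes of the AR-97Q library had more of the secreted protein gene Myoc (25.3 and 61.8 CPM, ratio 2.44, 2.02 to 2.96), of Egfem1 (2.42, 2.25 to 2.60), of Etnppl, an enzyme of phosphoethanolamine breakdown (2.03, 1.88 to 2.19), and of Angpt1, angiopoietin 1 (1.75, 1.56 to 1.95). The actin gene Actb (1.77, 1.62 to 1.93), the profilin gene Pfn2 (1.69, 1.44 to 1.99) and Rida (1.70, 1.46 to 1.98) were also higher. Lower were Il31ra, a cytokine receptor (2.85-fold, 2.24 to 3.66), Sez6l (1.96-fold, 1.59 to 2.43), the acetoacetyl-CoA synthetase gene Aacs (1.94-fold, 1.62 to 2.34), the chondroitin sulfate synthase gene Chsy1 (1.75-fold, 1.45 to 2.12), Lingo1 (1.72-fold, 1.44 to 2.08) and Shisa9, an auxiliary protein of AMPA receptors (1.72-fold, 1.55 to 1.90). Ptpn13, Grhl1, Bcl9l and Crkl were 1.68-, 1.68-, 1.65- and 1.63-fold lower. Of 3444 genes 21 met the size rule higher and 19 lower, and 62 met it after thinning (25 higher, 37 lower), of which 16 were shared with the unthinned set. Reactive astrocyte genes were above 1 in 7 of 7 measured members of 18 listed (median 0.32, 0.01 to 0.94; 0.65 after thinning). The intermediate filament genes Vim and Synm were at 1.91 (1.41 to 2.60) and 1.73, complement C3 at 1.78 (1.34 to 2.37) and Gfap at 1.23 (1.14 to 1.34). Cholesterol synthesis genes were below 1 in 20 of 23 members (median -0.25, -0.50 to -0.12, percentile 0.02), with Lss at 0.668 (0.552 to 0.805) and the low-density lipoprotein receptor gene Ldlr at 0.672 (0.600 to 0.751). Transport and homeostasis genes had a median of -0.05, with glutamine synthetase, Glul, at 1.33, Slc1a3 at 1.22 and Kcnj10 at 0.854. Androgen response genes had a median of 0.12 (-0.08 to 0.22; 0.01 with a floor of 50 CPM), with Maf at 1.81 and Fkbp5 at 1.78. A cluster led by Aqp4, Myoc and Gfap held 133 of 1328 AR-24Q and 126 of 1026 AR-97Q astrocytes. Neuronal transcripts were higher in AR-97Q astrocytes as well: the neurofilament genes Nefh (2.12, 1.74 to 2.59) and Nefm (1.78, 1.54 to 2.04) were among the largest ratios, and 16 of 18 genes of their list were above 1 (median 0.48; 0.20 with a floor of 50 CPM). Lists of free neuron and free oligodendrocyte RNA had medians of 0.55 (1.02 after thinning) and 0.63.

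Microglia of the AR-97Q library had more of Apobec3, a retrovirus restriction factor (2.22, 1.83 to 2.69), the annexin Anxa3 (305 and 664 CPM, ratio 2.17, 1.98 to 2.39), Fkbp5 (224 and 479 CPM, ratio 2.14, 1.92 to 2.40) and the glucocorticoid-induced leucine zipper gene Tsc22d3 (1.93, 1.46 to 2.59). Whrn (2.56, 2.13 to 3.09), the inflammasome receptor gene Naip6 (2.33, 1.74 to 3.14), Syngr1 (2.32, 1.93 to 2.79), the beta-1 adrenergic receptor gene Adrb1 (2.12, 1.62 to 2.81), the calcium channel gene Cacna1a (1.92, 1.54 to 2.42) and Cdc26 (1.89, 1.41 to 2.56) were also higher. On the lower side Cdk10 (1.80-fold, 1.31 to 2.5), Nars2 (1.76-fold, 1.27 to 2.44), Ibtk and Hnrnpab (1.69-fold each) came first, and Dse, Emc3, Ccdc192, Khnyn, Fam107b and Ddx21 were between 1.66- and 1.64-fold lower. After thinning, the Cdk10 ratio was 0.857. Of 3775 genes 25 met the size rule higher and 25 lower, and after thinning 23 and 9, of which 10 were shared with the unthinned set. Disease-associated microglia genes split 8 above to 5 below 1 (median 0.21, -0.12 to 0.58), with ferritin heavy chain, Fth1, at 1.72 (1.51 to 1.97), Clec7a at 1.50 (1.04 to 2.18) and Lpl at 1.52 (0.998 to 2.35). Homeostatic genes had a median of 0.00, with Selplg at 1.35, Tmem119 at 1.29 and Cx3cr1 at 0.928, and interferon response genes one of 0.06 (0.16 after thinning). In the androgen response list (median 0.09; 0.06 with a floor of 50 CPM) Fkbp5, Tsc22d3, Per1 (1.91), Sgk1 (1.56) and Zbtb16 (8 and 43 UMIs, 4.80) met the size rule higher and Ncoa4 (0.635, 0.454 to 0.885) lower. Oligodendrocyte transcripts, listed as free RNA, had a median of 0.71 in this class (0.24 with doublet calls kept, 0.19 after thinning). The neurofilament and axonal transport list had one of 0.59.

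Oligodendrocyte precursors of the AR-97Q library had more Angpt1 (49.2 and 128 CPM, ratio 2.61, 2.22 to 3.07), Errfi1 (2.17, 1.90 to 2.49), Fth1 (1.82, 1.63 to 2.04) and ENSMUSG00000095041 (2.81, 2.57 to 3.07). Rasgef1b was 2.28-fold lower (1.93 to 2.69), Lhfpl2 1.73-fold (1.49 to 2.00), Klhl22 1.65-fold (1.32 to 2.08) and Setx 1.64-fold (1.41 to 1.92). Of 3442 genes 11 met the size rule higher and 10 lower, and with doublet calls kept 9 and 4. The androgen response list had a median of 0.04 (0.13 after thinning), with Per1 at 1.82 (2.83 after thinning), Zbtb16 at 1.79 and Fkbp5 at 1.59 on the higher side and Ncoa4 at 0.640 (0.444 to 0.915) on the lower. In newly formed oligodendrocytes the synaptic scaffold gene Frmpd4 was at 10.7 and 77.5 CPM (7.22-fold higher, 4.26 to 13.1), ENSMUSG00000095041 at 3.04 (2.72 to 3.40), the class I histocompatibility gene H2-K1 at 2.23 (1.67 to 2.99) and Egflam at 2.18 (1.71 to 2.80). This class held 179 AR-24Q and 226 AR-97Q nuclei. Frmpd4 rested on few AR-24Q UMIs and had no thinned ratio. Golga3 was 2.36-fold lower (1.67 to 3.38), Shisa9 2.06-fold (1.73 to 2.47), Cyp2j9 1.87-fold (1.39 to 2.54) and Idh1 1.82-fold (1.36 to 2.44; thinned ratio 0.305). Chaperones were below 1 in 12 of 17 members (median -0.28, -0.58 to 0.05; -0.07 after thinning), with Stip1 at 0.5 and Hsph1 at 0.618. The androgen response median was 0.15, and -0.00 after thinning. Of 2665 genes 32 met the size rule higher and 37 lower, and 5 met it after thinning. Fewer genes of this small class could reach the minimum of 100 UMIs once thinned, so the fall decides nothing. Oligodendrocyte transcripts, listed as free RNA, had a median of 0.62 in precursors (0.01 with doublet calls kept). The same list had a median of 0.21 in newly formed oligodendrocytes (0.43 after thinning), where these can be the cells' own transcripts.

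Endothelial nuclei of the AR-97Q library had more Tsc22d3 (66.7 and 201 CPM, ratio 3.02, 2.01 to 4.68; 1.89 after thinning), Zbtb16 (2.85, 2.10 to 3.95; 4.67 after thinning), Pik3ip1 (2.17, 1.52 to 3.16) and the clock output gene Dbp (2.09, 1.42 to 3.15). Cdk19 was 1.79-fold lower (1.39 to 2.30), Plekhg1 1.68-fold (1.37 to 2.06), the transcription factor Elf1 1.65-fold (1.23 to 2.20) and Epc1 1.60-fold (1.2 to 2.14). Oxidative phosphorylation genes were above 1 in 26 of 35 members (median 0.26, 0.13 to 0.45) and proteasome genes in 25 of 31 (median 0.20, 0.10 to 0.40). Cox5a was at 1.60 (1.21 to 2.13), Uqcrh at 1.79 (1.21 to 2.70) and Psma7 at 1.41 (1.08 to 1.84). The oxidative phosphorylation median was 0.39 when each nucleus counted equally, and the proteasome median 0.30 after thinning. In the androgen response list (median 0.22, -0.12 to 0.41; 0.04 with doublet calls kept) Tsc22d3, Zbtb16, Per1 (2.04; 3.31 after thinning) and Sgk1 (1.88; 1.11 after thinning) met the size rule higher and Fkbp5 lower (0.490, 0.292 to 0.812). Of 1147 genes 50 met the rule higher and 15 lower. With doublet calls kept 196 genes met it, 98 each way, of which 48 were shared, so no lean to the higher side is drawn. Oligodendrocyte transcripts, listed as free RNA, were lower here (median -0.72, and -0.03 with doublet calls kept). Neuron transcripts, listed likewise, had a median of 0.57 that turned to -0.28 with doublet calls kept.

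Some genes differed the same way in several classes. ENSMUSG00000095041, a protein-coding gene model (AC149090.1 in GENCODE M21) on the unplaced scaffold JH584304.1 from 52190 to 59690, met the size rule in all 7 main classes, from 1.52-fold higher in microglia to 3.04-fold in newly formed oligodendrocytes. After thinning it was at 1.44 in microglia and 1.40 in endothelial nuclei, under the rule. Whether it shares reads with a similar copy elsewhere is not known from the counts. Fth1 (chromosome 19, 9980598 to 9985098), a subunit of the iron store ferritin, met the rule in 4 classes, with 1.58 (1.48 to 1.70) in astrocytes and 1.66 (1.36 to 2.03) in newly formed oligodendrocytes, and stood at 1.21 in oligodendrocytes, 1.29 in neurons and 1.19 in endothelial nuclei. In microglia, 1 of the 4, Fth1 was at 1.37 after thinning, under the rule. Zbtb16 (chromosome 9, 48654297 to 48836222, minus strand) and Errfi1 met it in 3 classes each, the latter at 1.62 (1.52 to 1.72) in astrocytes. In neurons Zbtb16 was at 0.881 (0.849 to 0.915), Fkbp5 at 0.936 (0.892 to 0.982; 1.02 after thinning) and Errfi1 at 0.889 (0.834 to 0.946; 1.00 with doublet calls kept). Tsc22d3, Angpt1, Fkbp5 and Anxa3 met the rule in 2 classes each. On the lower side Setx met the rule in 3 classes and lay between 0.549 and 0.730 in all 7, while Shisa9, Cracd and Crkl met it in 2 each. After thinning, Setx (0.734) and Crkl (0.738) in microglia and Shisa9 (0.684) in newly formed oligodendrocytes fell short of 1.5-fold. Thinned Setx was nearly level in newly formed oligodendrocytes (0.962). Ribosomal protein genes, a sign of cytoplasmic RNA in nuclear data, had medians above 0 in each of the 7 classes. These were 0.20 in oligodendrocytes (0.02 without possible free RNA), 0.11 in neurons (0.18 after thinning) and 0.27 in astrocytes (0.41 with a floor of 50 CPM). Precursors had 0.18 (0.08 after thinning) and endothelial nuclei 0.17 (0.37 after thinning). The intervals included 0 in microglia and newly formed oligodendrocytes, so no direction is drawn for the list there. In microglia the median was 0.09 (-0.02 to 0.17; 0.02 with at least 1000 genes), with 28 members above and 15 below 1. In newly formed oligodendrocytes it was 0.10 (-0.009 to 0.21; 0.04 after thinning), with 25 above and 17 below 1. Mitochondrially encoded genes had medians of 0.22 in oligodendrocytes and 0.30 in neurons (0.48 after thinning).

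**Figure D3:**
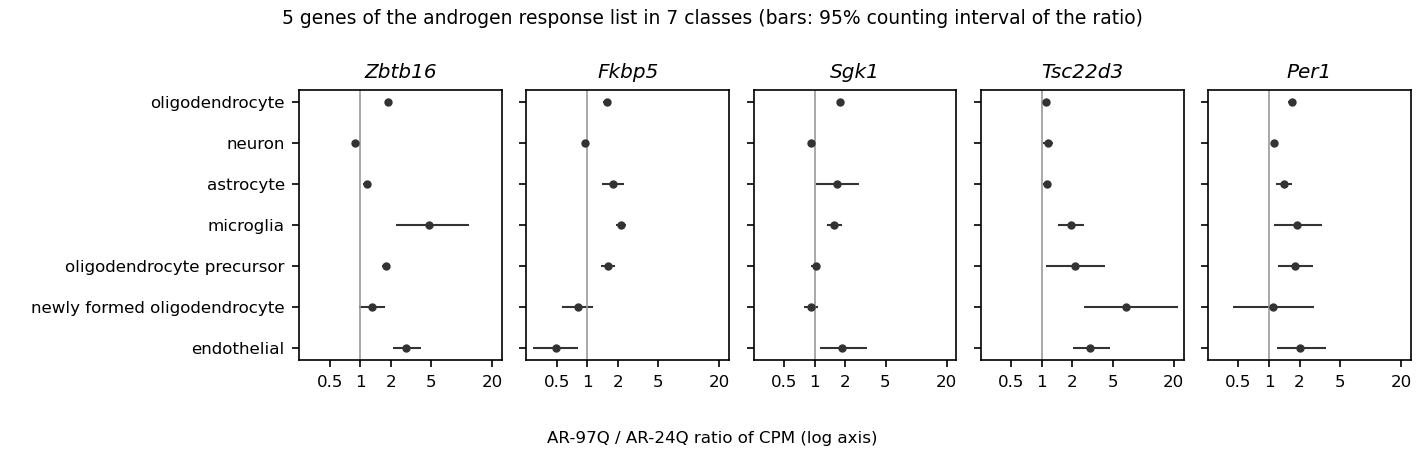
Ratio of CPM in the AR-97Q to that in the AR-24Q library (log axis) for Zbtb16, Fkbp5, Sgk1, Tsc22d3 and Per1, chosen from the androgen response list after their values were seen, in 7 classes. Points are ratios, bars 95% counting intervals and the grey line equality; Zbtb16 lies at 1.89 in oligodendrocytes and 0.881 in neurons, and Fkbp5 at 2.14 in microglia and 0.490 in endothelial nuclei.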

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

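The alternatives that kept mixed or unnamed neuron clusters in the neuron class were chosen after the data were seen; all others were fixed before. No paired analysis was possible because each genotype has 1 library. Of 1486 recomputed gene ratios (247 results) 1343 stayed inside the main 95% interval, 130 left it and 13, all of genes with an interval off 1, changed direction; of 572 list medians (66 results) the numbers were 528, 38 and 6, the last for lists outside the central 95% of random lists, of 83 ratios of shares (17 results) 74, 9 and 0, and of 49 counts of genes meeting the size rule (8 results) 32 stayed within 1.5 times. Ratios with an interval across 1 and medians of other lists that crossed to the other side are not among the 13 and the 6. Thinning leaves fewer UMIs, so part of its effect follows from its construction; other causes were not tested. The mean of each nucleus's own CPM has no counting interval and gave no count. The depth limits what can be said of small classes: at 107 cholinergic and motor neurons per library a thinned gene rests on few UMIs.

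Among shares, the neuron ratio was 0.897 with at least 1000 genes and 0.939 with mixed and unnamed neuron clusters counted. The microglia ratio was 1.01 with at least 200 genes and 1.08 with at least 1000. The ratio for mixed neurons was 1.26 with doublet calls kept, that for unnamed clusters 2.95 and 1.27 at the lower and higher gene minimum and 2.52 with centred components, and that for neurons without a subclass 1.03 at resolution 2.

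Counts of genes meeting the rule at 20 CPM and 50 UMIs, where more genes enter by construction, were 41 in oligodendrocytes, 7 in neurons, 135 in astrocytes, 194 in microglia, 117 in precursors, 234 in newly formed oligodendrocytes, 199 in endothelial nuclei and 145 in cholinergic and motor neurons. With doublet calls kept they were 2 in neurons, 13 in precursors and 196 in endothelial nuclei. Thinned, they were 4 in neurons, 62 in astrocytes, 32 in microglia, 5 in newly formed oligodendrocytes, 29 in endothelial nuclei and 3 in cholinergic and motor neurons. The minimum of 100 UMIs was kept, so fewer genes could enter after thinning, most of all in small classes. Thinned counts therefore do not show whether the difference of a gene was lost.

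Among gene ratios with an interval off 1, those that changed direction with thinning were Tsc22d3 in precursors (0.416), Fkbp5 in neurons (1.02), Ar in inhibitory neurons (0.888), Uchl1 in astrocytes (0.984), Hspa4l and Rpl10 in newly formed oligodendrocytes (1.14 and 1.98), Cldn11 in endothelial nuclei (1.06) and Vipr2 in cholinergic and motor neurons (0.667). Some with an interval across 1 crossed it too, such as Ar in cholinergic and motor neurons (0.889) and Anxa3 in astrocytes (0.432). With doublet calls kept they were Errfi1 in neurons (1.00), St18 in precursors (0.962) and Cldn11 and Meg3 in endothelial nuclei (1.18 and 0.809). With mixed neurons kept, Errfi1 was at 1.03 in neurons.

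List medians in neurons moved with scaling (TMM, then median-of-ratios): cholesterol synthesis -0.13 and -0.12, synaptic genes 0.13 and 0.13, ion channels 0.0429 and 0.0477, autophagy and lysosome -0.00948 and -0.00463 (thinned -0.00504), mitochondrially encoded 0.36 and 0.36 (thinned 0.48) and proteasome 0.0486 and 0.0534, which changed sign, as it did at 0.00383 when each nucleus counted equally. Median-of-ratios alone moved neuronal chaperones to -0.0393, neurofilament genes to 0.0230 and ribosomal protein genes to 0.18 (thinned 0.18). Cholesterol synthesis in excitatory neurons was -0.12 and -0.12.

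Thinned medians of cholinergic and motor neurons were -0.23 for chaperones, -0.80 for alpha motor neuron, 0.00 for synaptic and 0.26 for androgen response genes, the last from below 0. The androgen response median also changed sign in newly formed oligodendrocytes (-0.00376, thinned) and in oligodendrocytes (-0.0142, each nucleus counted equally). Ribosomal protein medians were 0.0233 in oligodendrocytes without possible free RNA and 0.41 in astrocytes at 50 CPM. In precursors they were 0.0801 thinned, 0.23 with TMM and 0.21 with median-of-ratios, and in endothelial nuclei 0.33 with nuclei counted equally, 0.34 with doublet calls kept and 0.37 thinned. The list of oligodendrocyte transcripts was at 0.81 in neurons with mixed neurons kept and at 0.24 (doublet calls kept) and 0.19 (thinned) in microglia. It was at 0.0126 in precursors with doublet calls kept. In endothelial nuclei it was at -0.21 with nuclei counted equally, -0.0290 with doublet calls kept and -0.11 thinned. The list of neuron transcripts, named for free RNA as well, was at 1.02 in thinned astrocytes. It changed sign to -0.28 in endothelial nuclei with doublet calls kept.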

Other observations

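The tests of time of day, of transgenic receptor activity, of free RNA and of the neighbours of Setx were chosen after the results were seen, as were the 5 hormone-responsive genes, the clock genes and the genes and list of the next paragraph. The tests of depth and of nuclei captured together were written before. Intervals of medians over pairs of gene and class treat pairs that share genes and libraries as separate. They therefore understate the spread.

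Immediate-early genes are those that neurons switch on within minutes of activity. Of 14 listed, 5 were measured in inhibitory neurons. All 5 were lower in the AR-97Q library (median log2 ratio -0.71, -1.57 to -0.34), and 4 met the size rule. Measured members needed 10 CPM in the higher library only, and members below that in both libraries are not covered. Fos was just over this floor in AR-24Q and under it in AR-97Q. Fos was 2.97-fold lower (416 and 105 UMIs, 2.40 to 3.72; thinned ratio 0.535), Btg2 2.05-fold (1.76 to 2.39), Junb 1.64-fold (1.40 to 1.92) and Egr1 1.61-fold (1.44 to 1.80), with Nr4a1 at 0.789 (0.695 to 0.894). In excitatory neurons Btg2 was at 0.551 (0.462 to 0.655), Nr4a1 at 0.642 (0.555 to 0.741) and Egr1 at 0.810 (0.698 to 0.940). In endothelial nuclei, the other class with this list measured, 6 of 9 members were above 1 (median 0.11, -0.48 to 0.51). In microglia Btg2 was at 1.28 (1.06 to 1.56) and Junb at 1.11 (0.808 to 1.52).

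Other genes, also chosen after the results were seen, moved one way in every class. Their agreement over classes is therefore no test. Il31ra, named by rule in astrocytes alone, was below 1 in all 7 classes, from 0.351 (0.273 to 0.447) in astrocytes to 0.551 (0.364 to 0.830) in endothelial nuclei. Zfp33b was above 1 in all 7, from 1.32 (0.353 to 5.98) in endothelial nuclei to 2.02 (1.42 to 2.88) in precursors, and so was Tatdn3, from 1.32 in endothelial nuclei to 1.96 (1.52 to 2.54) in astrocytes. The endothelial intervals of Zfp33b and Tatdn3 and the Tatdn3 intervals in microglia and newly formed oligodendrocytes include 1.

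Zbtb16, Fkbp5, Sgk1, Tsc22d3 and Per1, genes that respond to steroid receptors, were above 1 in 24 of 25 pairs of gene and class over oligodendrocytes, astrocytes, microglia, precursors and endothelial nuclei, the exception being Fkbp5 in endothelial nuclei, and 19 pairs were at least 1.5-fold. The tally keeps pairs at levels where free RNA is possible (Zbtb16 in microglia, Sgk1 in astrocytes, Tsc22d3 in precursors, Fkbp5 in oligodendrocytes and astrocytes, all counted among the 19), Tsc22d3 in precursors (15 and 29 UMIs) turned to 0.416 when thinned, Sgk1 in precursors was at 1.02 (0.924 to 1.13), and newly formed oligodendrocytes, left out, had Fkbp5 at 0.80 (0.561 to 1.14) and Sgk1 at 0.923 (0.783 to 1.09). For depth as the whole cause, a median log2 ratio under 0.2 after thinning to 1000 UMIs had been predicted. The thinned median was 0.76 (0.27 to 0.95) against 0.84 unthinned. The 0.58 set beforehand for ruling depth out lies inside the interval. Thinning keeps each nucleus's expected shares of UMIs, so a median near the unthinned one was likely whatever went with depth. Depth therefore stays open. Tissue taken at different times of day stays open: clock genes of opposite phase differed by 0.50 in the same classes, with medians of 0.28 (0.10 to 0.60) over 34 pairs and -0.22 (-0.54 to -0.12) over 11, but not alike in each class, with Per2 and Dbp at 2.53 and 1.64 in oligodendrocytes and 1.07 and 0.971 in astrocytes, and in neurons, outside the test, Per2 at 0.865, Tef at 0.936 and Nr1d2 at 0.999 beside Dbp at 1.40 and Arntl at 0.867. Activity of the transgenic receptor stays open as well. The 5 genes had a median of -0.0950 (lowest -0.18, highest 0.21) in neurons, the class with the most Ar of the 7 compared. But the transgene has 0 rows in the tables used here. The genotype itself, stress and hormone levels of the mice were not tested.

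Oligodendrocyte transcripts made up a larger share of UMIs in neurons, astrocytes, microglia and precursors of the AR-97Q library. The values below are shares at equal depth. Amounts per nucleus at full depth, which was lower in the AR-97Q library, were not compared. Thinned to 1000 UMIs, 19.0% of AR-97Q and 15.5% of AR-24Q neurons and 35.1% and 26.2% of precursors held any of them, with 1.37 as the median ratio of such UMIs over 5 classes. Without nuclei at 10 or more such UMIs the median was 1.246 (1.15 to 1.35), which decides nothing about nuclei captured together with an oligodendrocyte, because this split took out only 0.0485% of AR-24Q and 0.0491% of AR-97Q neurons and a deep nucleus joined to an oligodendrocyte can stay under it. Free RNA in the suspension would raise every class, and the lowest class ratio was 1.09 (0.887 to 1.34, endothelial) under the split, too wide to decide, and 0.787 (0.661 to 0.939) over all endothelial nuclei, of which 3.97% in AR-24Q and 0.84% in AR-97Q were at or over the split. These explanations cannot be told apart here, and no biological explanation was tested.

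Setx was lower and ENSMUSG00000095041 higher in each of 7 classes, though Setx was nearly level (0.962) in newly formed oligodendrocytes after thinning. Thinned to 1000 UMIs, the median absolute log2 ratio of the 2 genes was 0.64 (0.45 to 1.40), against 0.77 unthinned. It lay above the 0.4 set beforehand for ruling out a difference in depth. Thinning keeps each nucleus's expected shares of UMIs, so a value near the unthinned one was likely whatever went with depth. Depth is therefore not decided. A difference shared with the genes next to Setx, as a linked chromosome segment might give, is not decided: the 10 nearest measured genes, up to 620 kb away, had a median of -0.0504 (-0.26 to 0.06) in oligodendrocytes. Reads shared with similar copies and an inherited variant in either line stay open as untested, since reads and genotypes were not used here. The genotype named by the design stays open too.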
